A study of Solanum tuberosum with 12 samples.

How the data were processed

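Poly(A)-selected RNA from tubers of 4 potato cultivars was sequenced on an Illumina instrument, with 3 libraries per cultivar, per the labels' protocols. The deposited files are 12 in number, 1 per library, and all hold an identical table of the whole series, so they were read as 1 distinct file. Per the file headers, that table gives for each gene and library a deposited read count and a deposited FPKM value (fragments scaled by gene length and library total), together with a gene symbol and a description. The counts are whole numbers that differ in their total between libraries, so they were taken as raw. For the 8752 genes over 5 FPKM in every library, the gene length implied by the deposited count and FPKM varied between libraries by a median of 0.0133%, so each gene was scaled with one length throughout. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8 and HISAT2. The role and order of these tools, the genome build, the program that counted reads and its handling of strand and of reads shared between genes are not given in the sources used here.

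The table lists 42793 genes, of which 39028 have identifiers of the potato genome consortium (PGSC) and 3765 have assembled-transcript identifiers (MSTRG). At least 1 count was present for 29763 genes. Symbols were present for 22604 genes and descriptions for 37703. Gene names and functions are those printed in the deposited table, and many symbols come from the nearest annotated protein of another plant. No genome was used here, so no coordinates are given. Reads from near-identical copies may be split between them or assigned to one, which applies to the phenylalanine ammonia-lyase genes, the Kunitz-type protease inhibitors of the storage protein list and the 2 genes with the symbol CA1, and their separate values are uncertain. Overlapping and antisense genes cannot be told apart without strand.

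Cultivar and replicate number of each library were taken from the sample labels. The labels call the 3 libraries of a cultivar replicates without saying whether they came from separate plants, so p-values measure the spread between these libraries, which may be technical. No library pair had identical counts, and every pair of one cultivar differed by more than sampling noise (chi-square divided by degrees of freedom of at least 17.47). Replicate numbers are shared between cultivars but name no common batch, and libraries of equal number were not treated as pairs.

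Counts were analysed with edgeR 4.0.16 in R 4.3.3, with trimmed mean of M-values (TMM) normalization. Genes with low counts were removed with edgeR's expression filter at its defaults, which left 23091 tested genes. The quasi-likelihood model had one term per cultivar over all 12 libraries, and each adjusted p named as edgeR's comes from its quasi-likelihood F-test with Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p below 0.05 and an absolute log2 fold change of at least 1. The 6 pairwise comparisons were tested. For each of the 3 ways to pair the cultivars, a gene was counted as parting the pairs when it was called in all 4 pairwise tests between them in one direction. The average of Black kingkong and Red beauty against the average of the other 2 cultivars was tested as well, and the averages for the other pairings, with the gene lists in them, were added after the data were seen. The p-value of such an average measures the spread within cultivars, not the spread between cultivars of a class. Levels are CPM, counts scaled to a common library total with TMM factors, as mean ± SD over 3 libraries. The SE given with a log2 fold change is approximate. It is the absolute log2 fold change divided by the square root of the F statistic, and was not estimated by the model itself. Where all libraries of a cultivar had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, a ratio of CPM is given with the exact 95% binomial (Clopper-Pearson) interval of the summed counts. Floors and intervals cover counting error only.

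The comparisons, thresholds, 22 gene lists, processing alternatives and the rule for named genes were fixed before the data were examined. The lists cover phenylpropanoid entry, the flavonoid core, B-ring hydroxylases, late anthocyanin enzymes, anthocyanin transport, anthocyanin regulators, anthocyanin repressors, flavonols and proanthocyanidins, chlorogenic acid and lignin, carotenoids, starch synthesis, starch breakdown, sucrose, storage proteins, glycoalkaloids, photosynthesis, periderm and suberin, cell division, heat shock, defence, dormancy hormones and cytosolic ribosomes. Members were found by search terms in the deposited descriptions. The search for anthocyanin regulators also took zinc finger proteins with an AN1 domain, which are stress proteins, and it missed several factors of the pathway. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the 22 lists of a comparison, and again with an estimated correlation and with fry. Deposited KEGG pathway terms were tested by a hypergeometric test against the tested genes with a term.

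The rule for named genes took, in each main comparison, the 5 highest and 5 lowest called genes with a description, at least 10 CPM in the higher cultivar and no overlap between libraries. It also took up to 3 called members per list and direction by adjusted p, and every tested member of the flavonoid core, B-ring, late, transport and regulator lists at 10 CPM or more. The main comparisons were Black kingkong and Red beauty against Longshu No.7 and LK99, Black kingkong against Red beauty, and Longshu No.7 against LK99. After the values were seen, the same rule was applied to Black kingkong and LK99 against the others and to Black kingkong against LK99. A further 8 genes were chosen after their values were seen, namely FAOMT, CHI3, MYB308, the MYB113 gene described as MYBA1, BHLH, DTX35, WRKY44 and CYTB5-B. The 12 genes drawn in the plot of levels per library were also chosen after their values were seen.

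The alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no expression filter, the replicate number as a block, adjusted p alone, a stricter threshold (absolute log2 fold change of at least 2, adjusted p below 0.01), limma on log2(FPKM + 1) for genes of at least 1 FPKM in 3 libraries, only the libraries of the cultivars compared, and each of the 12 libraries left out. Another pseudocount was planned for the case that only FPKM could be used and was not run. The tests were tried on counts simulated for the 23091 tested genes, of which 22508 then passed the expression filter. These counts were drawn from each gene's mean over all libraries, the real library sizes and the spread that edgeR had fitted. They thus follow the model's own assumptions. Of 100 genes changed 3-fold, 63% were called for Black kingkong against LK99, 67% for Black kingkong against Red beauty and 62% for Black kingkong against Longshu No.7. Of 100 genes changed 8-fold, 83%, 82% and 83% were called in the same order, with 5, 1 and 4 false calls.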

Results

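Messenger RNA was sequenced from tubers of 4 cultivars of potato (Solanum tuberosum), named LK99, Longshu No.7, Red beauty and Black kingkong in the labels. There were 3 libraries per cultivar and 12 in all, from plants aged 150 days that had been grown side by side at one site. Per the labels, tubers were taken for anthocyanin determination as well as for sequencing. Anthocyanins are the red to purple pigments of coloured potato tubers. The labels state no skin or flesh colour for any cultivar, and no anthocyanin content was analysed here. Library titles hold the letters B for Black kingkong, R for Red beauty, Y for Longshu No.7 and W for LK99, without explanation. Gene counts summed to between 24367178 and 39425703 per library, the most in replicate 2 of Longshu No.7 and the fewest in replicate 3 of LK99. Libraries of one cultivar resembled each other more than those of any other cultivar, with a mean correlation of log2 CPM across genes of 0.978 within Black kingkong, 0.97 within Red beauty, 0.957 within Longshu No.7 and 0.955 within LK99. Between cultivars the mean correlation lay between 0.863, for Black kingkong and Longshu No.7, and 0.901, for Black kingkong and LK99.

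The cultivars differed in how much of the library went to storage and photosynthesis transcripts. Storage protein genes, such as patatins and protease inhibitors, took 2.96% ± 0.295 of counts in Black kingkong, 5.28% ± 0.171 in Red beauty, 12.8% ± 2.66 in Longshu No.7 and 9.02% ± 2.65 in LK99 (SD, n = 3). Photosynthesis genes took 0.0275% ± 0.000615, 0.0878% ± 0.0159, 0.37% ± 0.0827 and 0.0402% ± 0.00339 in the same order. The 10 most abundant genes held 5.77% ± 0.325 of counts in Black kingkong and 12.3% ± 2.74 in Longshu No.7. Replicate 3 of Longshu No.7 and replicate 3 of LK99 stood furthest from their own cultivar, with 15.32% and 13.07% of counts in the top 10 genes.

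Several anthocyanin pathway genes had abundant transcripts in the libraries labelled Black kingkong and LK99 and few or almost none in those labelled Red beauty and Longshu No.7. Of 11 genes of the flavonoid core, B-ring, late and transport lists at 10 CPM or more in both Black kingkong and LK99, 5 were below 1% of that level in both other cultivars, namely AN3, CHS2, DFRA, RT and GSTF11. This criterion was chosen after the values were seen. DFRA (PGSC0003DMG400003605), a dihydroflavonol 4-reductase at the entry to anthocyanin synthesis, averaged 72.6 ± 22 CPM in Black kingkong, 0.11 ± 0.19 in Red beauty, 0.0731 ± 0.0314 in Longshu No.7 and 352 ± 46 in LK99 (SD, n = 3). AN3 (PGSC0003DMG400003563), the flavanone 3-hydroxylase that supplies its substrate, followed the same order at 107 ± 28.8, 0.326 ± 0.278, 0.224 ± 0.0798 and 859 ± 198 CPM. CYP75A2 (PGSC0003DMG400000425), the flavonoid 3',5'-hydroxylase needed for blue and purple anthocyanins, averaged 78.5 ± 27.2, 4.14 ± 0.768, 3.58 ± 1.84 and 622 ± 120 CPM. CHS2 (PGSC0003DMG400019110), the chalcone synthase that starts flavonoid synthesis, averaged 19.8 ± 5.13, 0.0951 ± 0.086, 0.185 ± 0.171 and 1210 ± 278 CPM.

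Of the genes chosen after their values were seen, FAOMT, DTX35 and MYB308 were also higher in Black kingkong and LK99 than in the other cultivars. FAOMT, described as a flavonoid 3',5'-methyltransferase, averaged 366 ± 101 CPM in Black kingkong, 0.341 ± 0.0803 in Red beauty, 0.208 ± 0.234 in Longshu No.7 and 1910 ± 391 in LK99. DTX35 (PGSC0003DMG400010166), described as a transporter of the DETOXIFICATION family, averaged 93.1 ± 27.9 CPM in Black kingkong, 0.0787 in Red beauty and 0.0409 in Longshu No.7, and was 9610-fold lower in Longshu No.7 than in LK99 (edgeR adjusted p = 5.07e-08). MYB308 (PGSC0003DMG400013965), described as an R2R3-MYB transcription factor, averaged 43.2 ± 7.69, 0.831 ± 0.473, 1.33 ± 0.513 and 137 ± 35.2 CPM over the 4 cultivars. MYB113 (PGSC0003DMG400013966), described as MYBA1, went the other way, with 1.19 ± 0.403 CPM in Black kingkong, 18.1 ± 5.07 in Red beauty, 18.4 ± 12.1 in Longshu No.7 and 4.16 ± 0.52 in LK99.

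**Figure D1:**
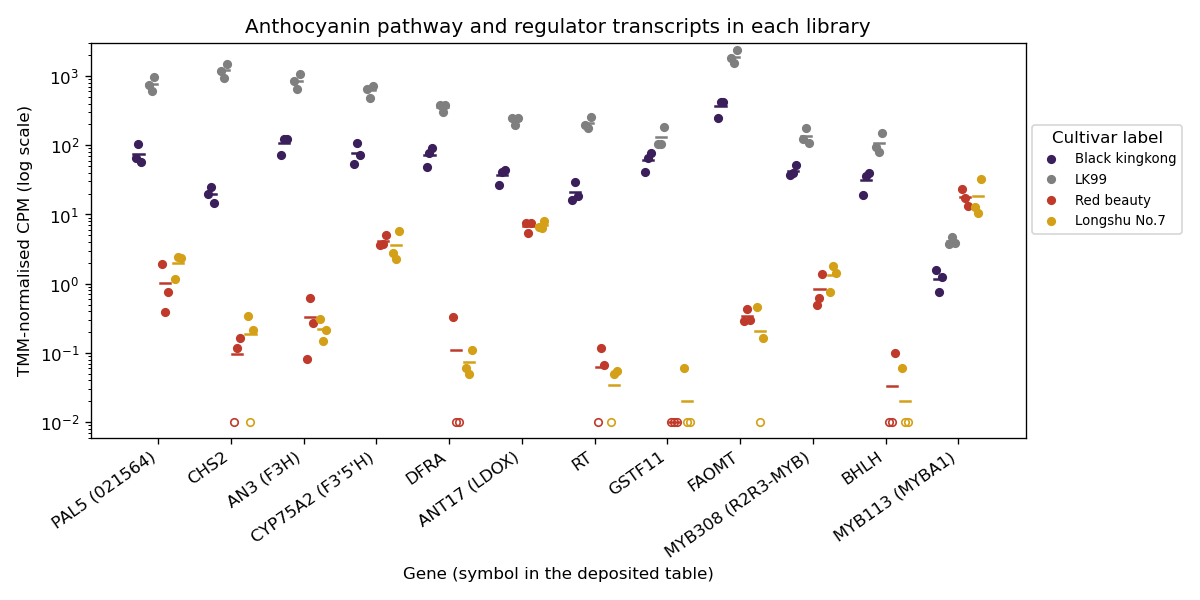
The plot shows the TMM-scaled CPM of 12 genes on a log axis for the 12 libraries, coloured by cultivar, with points for libraries, short lines for cultivar means and open circles, drawn at 0.01, for libraries at 0. The enzyme genes and MYB308 lie high in the libraries labelled Black kingkong and LK99 and low in the other 6, while MYB113 has the opposite order.

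Black kingkong and Red beauty carry a colour in their names, and the first comparison set these cultivars against Longshu No.7 and LK99. The 341 genes that parted the pairs, called in all 4 pairwise tests in one direction, included 0 of the 37 tested genes of the flavonoid core, B-ring, late anthocyanin and transport lists. At an unadjusted p below 0.05 in all 4 tests, edgeR, DESeq2 and limma on log2(FPKM + 1) also gave 0. Protease inhibitors of the storage protein list were among them, on both sides. CDI (PGSC0003DMG400010128), a proteinase inhibitor of the tuber, averaged 1460 ± 177 CPM in Black kingkong and 5110 ± 650 in Red beauty against 17000 ± 4310 in Longshu No.7 and 14100 ± 6000 in LK99 (n = 3), a 5.66-fold lower average (log2 fold change -2.5, SE 0.204, edgeR adjusted p = 6.45e-06). A second inhibitor, GSPO-B1 (PGSC0003DMG400008546), had the opposite order, at 670 ± 291 and 166 ± 51.6 CPM against 31.6 ± 11.7 and 21.9 ± 21.5 (log2 fold change 3.66, edgeR adjusted p = 0.000115). STP-1, an alpha-glucan phosphorylase, which degrades starch, averaged 862 ± 215 and 1140 ± 301 CPM against 2440 ± 234 and 4320 ± 1110 (log2 fold change -1.71, SE 0.178, edgeR adjusted p = 2.99e-05).

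Of the genes that parted these pairs, TOM20, described as a subunit of the mitochondrial import receptor, averaged 27 ± 2.36 CPM in Black kingkong and 43.2 ± 8.45 in Red beauty, against 0.389 ± 0.674 in Longshu No.7 and 0 in LK99. A gene described as zinc-regulated protein 8-like (PGSC0003DMG400002678) averaged 31.1 ± 8.72 and 33.7 ± 3.84 CPM against 2.93 ± 0.634 and 1.14 ± 0.362, a 17.7-fold higher average (edgeR adjusted p = 5.13e-07). VPS39, described as a vacuolar sorting protein, averaged 0.831 ± 0.288 and 2.21 ± 0.391 CPM against 16.1 ± 1.53 and 12.3 ± 0.693, 10.3-fold lower (edgeR adjusted p = 5.13e-07). SMC4, a chromosome condensation protein, was 26.6-fold lower (edgeR adjusted p = 5.29e-06), at 0.161 ± 0.0511 and 0.819 ± 0.493 CPM against 9.37 ± 2.02 and 10.3 ± 5.54. TAS14, a dehydrin induced by abscisic acid, was 15.4-fold lower (edgeR adjusted p = 8.09e-06), most of it from Longshu No.7 at 158 ± 94.6 CPM. WIN1, a wound-induced chitin-binding protein, was 4.22-fold higher (edgeR adjusted p = 9.94e-05), at 214 ± 15.3 CPM in Black kingkong. CCD1, a carotenoid cleavage dioxygenase, was lowest in Black kingkong at 4.67 ± 2.34 CPM and highest in Longshu No.7 at 106 ± 3.31 (log2 fold change of the average -2.82, edgeR adjusted p = 1.81e-06).

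Where one pair of counts is given for a list, the counts adjusted over the list alone were equal. By gene list, the average of Black kingkong and Red beauty was lower than that of the other cultivars for phenylpropanoid entry, the flavonoid core, storage proteins and photosynthesis. Of 16 tested phenylpropanoid entry genes, 9 were lower (camera adjusted p = 1.69e-06), and of 9 flavonoid core genes 3 were lower (camera adjusted p = 0.0169). Storage proteins had 18 of 48 lower and 4 higher, also when adjusted over the list alone (camera adjusted p = 4.5e-06). Photosynthesis had 48 of 69 lower by either adjustment (camera adjusted p = 6.05e-28). Cytosolic ribosome genes passed as higher (camera adjusted p = 0.0199) with only 4 of 233 called higher and 2 lower, or 4 and 1 adjusted over the list alone. None of these 5 list calls held with an estimated correlation (adjusted p = 0.154, 0.111, 0.111, 0.109 and 0.753 with an estimated correlation, in that order). Black kingkong against Longshu No.7 alone went the other way for the first 2 lists. Phenylpropanoid entry then had 9 of 16 higher and 1 lower (camera adjusted p = 0.000206, adjusted p = 0.178 with an estimated correlation). The flavonoid core had 3 of 9 higher and 2 lower (camera adjusted p = 0.0376, adjusted p = 0.131 with an estimated correlation).

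The other pairings of the cultivars parted more genes in one case and fewer in the other. Black kingkong and LK99 against Red beauty and Longshu No.7 parted 730 genes, 401 higher and 329 lower, while Black kingkong and Red beauty against the others parted 341, with 227 of them lower. The remaining pairing, Black kingkong and Longshu No.7 against Red beauty and LK99, parted 156 genes, 74 higher and 82 lower. For this pairing limma on log2(FPKM + 1) gave 59.1% higher calls (55 higher, 38 lower) against 47.4%. Each pairing gives 2 comparisons of differences without a shared library, and these did not all point one way. Every such comparison recurs in another pairing with the sign of a difference reversed. Genes counted as together in a pairing are then counted as opposite in the other, so their counts are not separate results. Black kingkong minus Red beauty and LK99 minus Longshu No.7 were higher together for 583 genes and lower together for 586, where independent lists would share 177 and 163, and opposite for 293 where 339 would be. Black kingkong minus Longshu No.7 and LK99 minus Red beauty were together for 591 and 498 genes, against 245 and 208, but also opposite for 600 against 476. For Black kingkong with Red beauty, the differences Black kingkong minus LK99 and Red beauty minus Longshu No.7 were higher together for 226 and lower together for 494, against 88 and 186, and opposite for 332 against 256. In its other comparison, Black kingkong minus Longshu No.7 and Red beauty minus LK99 were together for 218 and 382, against 162 and 313, and far more often opposite, for 1089 against 452. For Black kingkong with Longshu No.7, the differences Black kingkong minus Red beauty and Longshu No.7 minus LK99 were together for only 131 and 162 genes, against 169 and 171, and opposite for 1169 against 340. Black kingkong minus LK99 and Longshu No.7 minus Red beauty were together for 141 and 191, against 125 and 131, and opposite for 720 against 274.

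Among the genes that parted Black kingkong and LK99 from the others, flavonoid biosynthesis was the most enriched KEGG pathway on the higher side, with 12 of its 31 genes where 0.509 were due by chance (hypergeometric adjusted p = 2.22e-12). Phenylpropanoid biosynthesis had 16 genes where 1.85 were due (adjusted p = 1.18e-09). On the lower side photosynthesis had 23 of 65 genes (adjusted p = 3.84e-22) and the antenna proteins 10 of 27 (adjusted p = 1.81e-09). On this average, added after the data were seen, phenylpropanoid entry had 13 of 16 genes higher and 1 lower by either adjustment, with camera adjusted p = 7.39e-20 (adjusted p = 0.0066 with an estimated correlation). The flavonoid core had 3 of 9 higher and 1 lower by either adjustment, with camera adjusted p = 1.02e-09 (adjusted p = 0.00182 with an estimated correlation). It did not pass with the replicate number as a block (camera adjusted p = 0.111). Late anthocyanin enzymes had 4 of 22 higher and 7 lower by either adjustment and did not pass (camera adjusted p = 0.147). B-ring hydroxylases had 1 of 5 higher and 0 lower (camera adjusted p = 0.0219, adjusted p = 0.188 with an estimated correlation). For Black kingkong and Red beauty against the others, the enriched pathways were plant hormone signal transduction among higher genes, with 7 of 228 (adjusted p = 0.000548), and tyrosine metabolism among lower genes, with 4 of 39 (adjusted p = 0.0271).

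**Figure D2:**
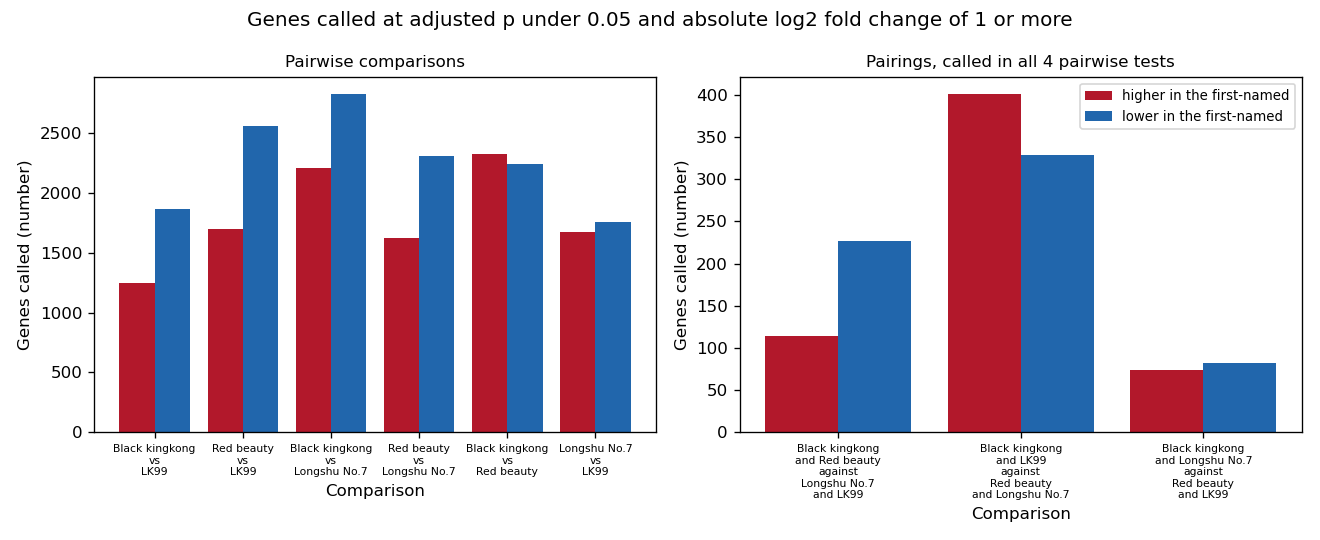
Bars show the number of called genes, higher and lower, in each of the 6 pairwise comparisons and the number that parted each of the 3 pairings in all 4 pairwise tests. Black kingkong against Longshu No.7 had the most calls of the pairwise comparisons, and Black kingkong with LK99 parted more genes from the other cultivars than either other pairing.

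In Black kingkong against Red beauty, several anthocyanin pathway genes were higher in Black kingkong, while late anthocyanin enzymes as a list went both ways and most photosynthesis genes were lower. DFRA was 689-fold higher (log2 fold change 9.43, SE 0.532, edgeR adjusted p = 2.32e-07), AN3 was 322-fold higher (8.33, SE 0.424, edgeR adjusted p = 9.75e-08) and CHS2 was 190-fold higher (7.57, SE 0.568, edgeR adjusted p = 1.88e-06). RT (PGSC0003DMG400024344), described as an anthocyanidin 3-O-glucosyltransferase, was 320-fold higher at 21.4 ± 7.09 against 0.0617 ± 0.0592 CPM, and CYP75A2 was 18.9-fold higher. ANT17, the leucoanthocyanidin dioxygenase that forms anthocyanidins, differed less, with 37.3 ± 9.38 against 6.79 ± 1.25 CPM (5.48-fold, edgeR adjusted p = 4.61e-06). GSTF11, a glutathione S-transferase of the class that carries anthocyanins to the vacuole and the single tested member of the transport list, had 61.2 ± 18 CPM in Black kingkong and 0 in Red beauty, at least 1630-fold higher (edgeR adjusted p = 6.18e-07). Tested as a list of 1 gene, transport passed (camera adjusted p = 1.63e-07). This repeats the result of GSTF11, and a single gene has no correlation to estimate.

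Phenylpropanoid entry had 10 of 16 members higher and 1 lower, or 11 and 1 adjusted over the list alone (camera adjusted p = 1.36e-08, adjusted p = 0.0578 with an estimated correlation). A phenylalanine ammonia-lyase copy, PAL5 (PGSC0003DMG402021564), had 75.8 ± 25.1 against 1.03 ± 0.801 CPM, while TPA1, also described as a phenylalanine ammonia-lyase, was lower in Black kingkong (log2 fold change -2.62, SE 0.463, edgeR adjusted p = 0.00103). The flavonoid core had 3 of 9 higher and 0 lower, or 4 and 0 adjusted over the list alone (camera adjusted p = 1.79e-05), a call that held with an estimated correlation. B-ring hydroxylases had CYP75A2 higher out of 5 by either adjustment, and the list's median was below 0 while its mean and test were above (camera adjusted p = 0.476). Late anthocyanin enzymes went both ways, with 4 of 22 higher and 8 lower, or 4 and 9 adjusted over the list alone (camera adjusted p = 0.54). The lower ones included glycosyl- and acyltransferases, such as GT6 (PGSC0003DMG400015327), a flavonoid 3-O-glucosyltransferase, at 5.35 ± 2.21 against 51 ± 8.88 CPM, and the acyltransferase 5MAT1 (PGSC0003DMG400026632), at 0.261 against 8.24 ± 0.652 CPM. Regulators had 1 of 15 higher and 2 lower by either adjustment (camera adjusted p = 0.721), with a test below 0 and a median above it. Repressors had 3 of 9 higher (camera adjusted p = 0.0586) and flavonols and proanthocyanidins 3 of 12 higher and 1 lower (camera adjusted p = 0.713). Among the latter ANR, an anthocyanidin reductase that diverts anthocyanidins to proanthocyanidins, was 4.31-fold higher (edgeR adjusted p = 0.000326).

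Photosynthesis had 50 of 69 members lower in Black kingkong than in Red beauty and 1 higher, or 52 and 1 adjusted over the list alone (camera adjusted p = 9.33e-38), a call that held with an estimated correlation. PSBP, a subunit of the oxygen-evolving complex, averaged 0.168 ± 0.0517 against 35.8 ± 6.99 CPM (log2 fold change -7.68, SE 0.305, edgeR adjusted p = 2.96e-08), and CAP10B, a chlorophyll-binding antenna protein, 1.68 ± 0.484 against 74.3 ± 16.6 CPM. Storage proteins went both ways, with 9 of 48 higher and 13 lower, or 9 and 14 adjusted over the list alone (camera adjusted p = 0.0575). PIN2K, a proteinase inhibitor II, averaged 127 ± 33.6 CPM in Black kingkong against 4220 ± 780 in Red beauty (33.3-fold lower, edgeR adjusted p = 8.91e-07), and GSPO-B1 (PGSC0003DMG400010170), a Kunitz-type inhibitor, 704 ± 118 against 35.1 ± 10.1 CPM (20.1-fold higher). CEVI57, another proteinase inhibitor, had 0 counts in Black kingkong and 26.6 ± 4.74 CPM in Red beauty, at least 781-fold lower.

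Defence genes had 30 of 96 higher in Black kingkong and 7 lower, or 32 and 7 adjusted over the list alone (camera adjusted p = 0.0392, adjusted p = 0.374 with an estimated correlation). GLUB1, a basic beta-glucanase that attacks fungal walls, had 21.6 ± 9.8 CPM against 0, at least 574-fold higher (edgeR adjusted p = 9.01e-06), and Cht1, a class I chitinase, had 30.3 ± 17.2 against 0.0822 ± 0.142 CPM. SN2, the antimicrobial peptide snakin-2, was 15.7-fold lower at 101 ± 32.9 against 1580 ± 794 CPM (edgeR adjusted p = 6.01e-05). Heat shock genes had 21 of 85 lower and 2 higher by either adjustment (camera adjusted p = 0.0048, adjusted p = 0.374 with an estimated correlation), among them the chaperone HSP70 (PGSC0003DMG400027750) at 101 ± 8.69 against 317 ± 24.8 CPM. Carotenoid genes had 8 of 41 lower and 2 higher by either adjustment (camera adjusted p = 0.183). PSY1, the phytoene synthase that starts carotenoid synthesis, was 2.88-fold lower (edgeR adjusted p = 6e-05), and CCD4, a carotenoid cleavage dioxygenase, was 39.5-fold higher (edgeR adjusted p = 0.000178). Chlorogenic acid and lignin genes had 6 of 33 higher and 1 lower, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.168), led by CCR1 (MSTRG.2276), a cinnamoyl-CoA reductase, at 168 ± 16.7 against 47.3 ± 4.79 CPM.

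The remaining lists did not pass camera for Black kingkong against Red beauty. Sucrose genes had 3 of 37 higher and 4 lower (camera adjusted p = 0.84), with a median above 0 and a mean below it. Starch breakdown had 2 of 26 higher and 3 lower (camera adjusted p = 0.84), again with a median above 0 and a test below it, and starch synthesis 1 of 16 lower (camera adjusted p = 0.173). Periderm and suberin genes, markers of tuber skin, had 2 of 14 each way (camera adjusted p = 0.713). Glycoalkaloid genes had 3 of 6 higher and 2 lower (camera adjusted p = 0.505). Dormancy hormone genes had 1 of 37 higher and 8 lower, or 3 and 8 adjusted over the list alone (camera adjusted p = 0.267). Cell division genes had 8 of 63 higher and 5 lower, which became 2 higher and 4 lower with limma on log2(FPKM + 1) (camera adjusted p = 0.54), and cytosolic ribosome genes had 16 of 233 higher and 9 lower (camera adjusted p = 0.0702). Over all genes, Black kingkong had 2330 higher and 2243 lower than Red beauty, 4573 in all. The near balance turned slightly with DESeq2 size factors, to 2260 higher and 2293 lower, and limma on log2(FPKM + 1) gave 1739 higher and 1199 lower.

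In Longshu No.7 against LK99, several anthocyanin pathway genes were lower in Longshu No.7, others of the same lists were higher, and most photosynthesis genes were higher. DFRA was 4570-fold lower (log2 fold change -12.16, SE 0.547, edgeR adjusted p = 3.31e-08), CHS2 was 6790-fold lower (-12.73, SE 0.557, edgeR adjusted p = 3.31e-08) and AN3 was 3840-fold lower (-11.91, SE 0.462, edgeR adjusted p = 1.85e-08). CYP75A2 was 174-fold lower and ANT17 32.6-fold lower, at 7.05 ± 0.892 against 230 ± 27.9 CPM. GSTF11 had 2 counts over the libraries of Longshu No.7, and the ratio of LK99 to Longshu No.7 was 7100 (95% interval 1960 to 58600). Transport as a list of 1 gene passed (camera adjusted p = 1.45e-10), which repeats the result of GSTF11. BHLH, described as a basic helix loop helix factor, the family that partners MYB factors in pigment regulation, had a ratio of 5920 (95% interval 1640 to 48900), and MYB308 was 102-fold lower (edgeR adjusted p = 1.48e-07). MYB113 was 4.43-fold higher in Longshu No.7 (log2 fold change 2.15, SE 0.398, edgeR adjusted p = 0.00184).

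Phenylpropanoid entry had 12 of 16 lower in Longshu No.7 and 1 higher, or 13 and 1 adjusted over the list alone (camera adjusted p = 9.86e-19), and 4CL3, a 4-coumarate-CoA ligase, was 48.6-fold lower (edgeR adjusted p = 1.16e-07). The flavonoid core had 3 of 9 lower, CHS2, CHS1B and AN3, and 3 higher, by either adjustment (camera adjusted p = 1.46e-06). The higher ones included DLO2, described as a flavonol synthase or flavanone 3-hydroxylase, at 66.2 ± 14.2 against 7.69 ± 1.81 CPM (8.6-fold, edgeR adjusted p = 2.39e-06). Late anthocyanin enzymes had 5 of 22 lower and 4 higher, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.000169). Flavonols and proanthocyanidins had 5 of 12 higher and 0 lower by either adjustment (camera adjusted p = 0.000169), with ANR 7.01-fold higher (edgeR adjusted p = 6.66e-05) and PLR_Lp1, an isoflavone reductase homolog, 4.95-fold higher (edgeR adjusted p = 3.06e-06). These 4 list calls held with an estimated correlation. For the flavonoid core and late enzymes the test pointed to lower values in Longshu No.7. Both lists did not pass with the replicate number as a block (camera adjusted p = 0.21 for each). B-ring hydroxylases had 2 of 5 lower (camera adjusted p = 0.00212, adjusted p = 0.0762 with an estimated correlation) and repressors 4 of 9 lower and 1 higher (camera adjusted p = 0.000169, adjusted p = 0.0644 with an estimated correlation). The lower repressors included MYB3, with 0 counts in Longshu No.7 and 39.1 ± 8.27 CPM in LK99 (at least 1430-fold lower), and LBD38, 12.7-fold lower (edgeR adjusted p = 4.58e-05). Regulators had 1 of 15 each way (camera adjusted p = 0.489), and TTG1 (PGSC0003DMG400000561), the WD40 partner of MYB and bHLH factors, had 12.1 and 16 CPM without a call. Another TTG1 (PGSC0003DMG400026477) was lower in Longshu No.7, at 3.43 against 8.83 CPM (log2 fold change -1.36, SE 0.228, edgeR adjusted p = 0.000978). GL3, of the bHLH family, was higher (log2 fold change 1.38, edgeR adjusted p = 0.014), a call lost without replicate 1 of LK99 (adjusted p = 0.0508).

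Photosynthesis had 58 of 69 members higher in Longshu No.7 and 1 lower, or 61 and 1 adjusted over the list alone (camera adjusted p = 5.85e-76), a call that held with an estimated correlation. LHCB5, a light-harvesting protein of photosystem II, averaged 212 ± 42.7 against 0.664 ± 0.345 CPM (log2 fold change 8.32, SE 0.37, edgeR adjusted p = 3.31e-08), and PSBP 169 ± 40.3 against 5.36 ± 0.942 CPM. CAB37, another chlorophyll-binding protein, had 17.1 ± 8.55 CPM against 0, at least 426-fold higher. Storage proteins had 13 of 48 higher and 2 lower, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.00227, adjusted p = 0.147 with an estimated correlation), and GSPO-B1 (PGSC0003DMG400010170) was 23.7-fold higher at 119 ± 59.8 against 5.01 ± 1.06 CPM. PLP2, a patatin-like protein, was 3.19-fold higher (edgeR adjusted p = 3.32e-05). Carotenoid genes had 9 of 41 higher and 2 lower, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0233, adjusted p = 0.147 with an estimated correlation), with CRTL-E-1, the lycopene epsilon cyclase that leads to lutein, at 22.1 ± 11.1 against 2.72 ± 0.518 CPM. Heat shock genes had 14 of 85 higher and 3 lower (camera adjusted p = 0.0233, adjusted p = 0.381 with an estimated correlation), with HSP23 at 162 ± 24.2 against 46.5 ± 3.69 CPM. Cytosolic ribosome genes had 11 of 233 higher and 2 lower (camera adjusted p = 0.0114, adjusted p = 0.761 with an estimated correlation), with RPS4 (MSTRG.16674) at 24.4 against 2.76 CPM.

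The remaining lists did not pass camera for Longshu No.7 against LK99. Sucrose genes had 6 of 37 higher and 4 lower, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.112), with TIV1, the vacuolar invertase that splits stored sucrose, 8.47-fold higher (edgeR adjusted p = 0.000195). Starch synthesis had 0 of 16 called by edgeR, with 6 at an unadjusted p below 0.05, and 0 by DESeq2 or limma (camera adjusted p = 0.331), and starch breakdown 2 of 26 lower (camera adjusted p = 0.699). Chlorogenic acid and lignin genes had 5 of 33 higher and 8 lower (camera adjusted p = 0.126), with CCR1 (PGSC0003DMG400019825) 14.2-fold lower. Defence genes had 7 of 96 higher and 10 lower, or 8 and 11 adjusted over the list alone (camera adjusted p = 0.489), which became 6 higher and 4 lower with limma on log2(FPKM + 1). STH-2, a pathogenesis-related protein, was 5.06-fold lower (edgeR adjusted p = 0.00023). Dormancy hormone genes had 3 of 37 higher and 6 lower (camera adjusted p = 0.862), with a median above 0 and a mean below it, and 3 higher and 1 lower with limma on log2(FPKM + 1). Of these genes GA20OX1, a gibberellin 20-oxidase, was 20.3-fold lower in Longshu No.7 and DRM1, an auxin-repressed dormancy marker, 13.9-fold higher. Periderm and suberin genes had 1 of 14 higher and 5 lower (camera adjusted p = 0.12). Cell division genes had 4 of 63 higher and 7 lower, a count that turned to 2 higher and 1 lower with limma on log2(FPKM + 1) (camera adjusted p = 0.816), and glycoalkaloid genes 1 of 6 higher (camera adjusted p = 0.126). Over all genes 1673 were higher and 1757 lower in Longshu No.7, 3430 in all. The majority turned with limma on log2(FPKM + 1), to 1242 higher and 1010 lower, and without an expression filter, to 1759 and 1732.

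**Figure D3:**
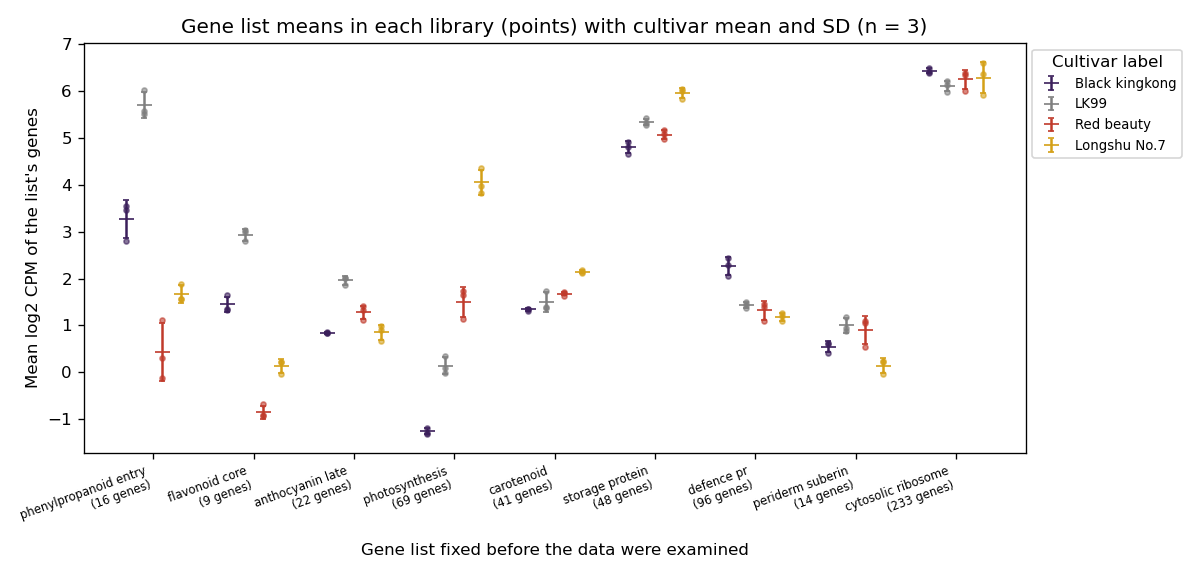
The plot shows the mean log2 CPM of 9 gene lists for each library, with the cultivar mean and SD over 3 libraries. The photosynthesis mean of every Longshu No.7 library lies above that of every other library, and the phenylpropanoid entry mean is highest in LK99.

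Black kingkong and LK99, which resembled each other most, differed in 3112 genes, 1249 higher and 1863 lower in Black kingkong. With limma on log2(FPKM + 1) the share of higher calls was 53.6% (1096 higher, 948 lower) against 40.1%. Some anthocyanin pathway genes were lower in Black kingkong, with CHS2 61.3-fold lower (edgeR adjusted p = 2.05e-06), RT 9.78-fold lower (edgeR adjusted p = 7.69e-06), AN3 8.06-fold lower (edgeR adjusted p = 2.98e-05) and DFRA 4.86-fold lower (edgeR adjusted p = 0.000301). DFR (PGSC0003DMG400021805), another dihydroflavonol 4-reductase, had 0 counts in Black kingkong and 2.09 CPM in LK99, at least 61.5-fold lower. Phenylpropanoid entry had 12 of 16 lower by either adjustment (camera adjusted p = 5.73e-09, adjusted p = 0.118 with an estimated correlation). The flavonoid core had 3 of 9 lower (camera adjusted p = 4.77e-06) and late enzymes 7 of 22 lower (camera adjusted p = 2.21e-05), and both calls held with an estimated correlation. B-ring hydroxylases had 2 of 5 lower (camera adjusted p = 0.0269, adjusted p = 0.281 with an estimated correlation). GSTF11 was 2.13-fold lower (log2 fold change -1.09, edgeR adjusted p = 0.0194), a call lost without replicate 1 or 2 of Black kingkong or replicate 3 of LK99.

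Outside the pigment genes, some starch and storage protein genes were lower in Black kingkong than in LK99. PHO1, the plastid alpha-glucan phosphorylase, averaged 1450 ± 202 against 5570 ± 1250 CPM (3.84-fold, edgeR adjusted p = 0.000107), and AGPS1 (PGSC0003DMG400000735), of the ADP-glucose pyrophosphorylase that feeds starch synthesis, 349 ± 87.3 against 931 ± 170 CPM (2.67-fold, edgeR adjusted p = 0.00124). Starch synthesis had 2 of 16 lower (camera adjusted p = 0.00519, adjusted p = 0.371 with an estimated correlation). Starch breakdown, the list of PHO1, had 7 of 26 lower and 1 higher but did not pass camera (adjusted p = 0.324), with a median log2 fold change of 0.04 and a mean of -0.36. Storage proteins had 18 of 48 lower and 7 higher (camera adjusted p = 0.000733, adjusted p = 0.218 with an estimated correlation), with PIN2K 37-fold lower and GSPO-B1 (PGSC0003DMG400010170) 141-fold higher. Photosynthesis had 31 of 69 lower, or 33 adjusted over the list alone (camera adjusted p = 9.06e-13, adjusted p = 0.184 with an estimated correlation). Defence genes had 19 of 96 higher and 4 lower (camera adjusted p = 0.00734, adjusted p = 0.346 with an estimated correlation), with CHN50, a chitinase, 15.9-fold higher and PTI6, an activator of defence genes, 3.25-fold higher. Ribosome genes had 18 of 233 higher and 2 lower, or 18 and 3 adjusted over the list alone (camera adjusted p = 2.6e-06, adjusted p = 0.583 with an estimated correlation).

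Black kingkong against Longshu No.7 had 5038 called genes, 2209 higher and 2829 lower. Photosynthesis had 65 of 69 lower in Black kingkong and 1 higher by either adjustment (camera adjusted p = 3.96e-83) and storage proteins 25 of 48 lower and 5 higher, or 27 and 6 adjusted over the list alone (camera adjusted p = 4.78e-07), and both calls held with an estimated correlation. Red beauty against LK99 had 4254 called genes, 1696 higher and 2558 lower. Phenylpropanoid entry had 13 of 16 lower in Red beauty and 0 higher, or 14 and 1 adjusted over the list alone (camera adjusted p = 3.06e-23), and the flavonoid core 5 of 9 lower (camera adjusted p = 1.99e-12), calls that held with an estimated correlation. Photosynthesis had 34 of 69 higher in Red beauty and 2 lower (camera adjusted p = 2.32e-14, adjusted p = 0.181 with an estimated correlation). Red beauty against Longshu No.7 had 3933 called genes, 1625 higher and 2308 lower, with photosynthesis lower in Red beauty for 54 of 69 and 0 higher, or 55 and 1 adjusted over the list alone (camera adjusted p = 3.92e-34, adjusted p = 0.073 with an estimated correlation). The flavonoid core was lower in Red beauty for 3 of 9 genes (camera adjusted p = 0.0616), a list that did not pass.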

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

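The runs without replicate 3 of Longshu No.7 and of LK99 together and the added averages and lists were chosen only after the result was seen. Counts of called genes stayed within 1.5 times of those reported under DESeq2 size factors, the DESeq2 Wald test, no expression filter, only the libraries of the cultivars compared and the replicate block. Of 9964 values of named genes under all alternatives, 9553 kept their side of the threshold, 365 fell short of it and 46 newly passed. Where the gene was called in the main run, 0 turned direction. Changes of direction in genes not called there were not counted. Depth limits genes near the floor of 3 counts. Fitted folds are left out where a cultivar compared had 3 counts or fewer. They are given for genes a little above that floor, such as DTX35, RT and DFRA, where the size of the fold is uncertain. DESeq2 left 3488 of 26275 genes without an adjusted p in each comparison.

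Listed as Black kingkong against LK99, Red beauty against LK99, Black kingkong against Longshu No.7, Red beauty against Longshu No.7, Black kingkong against Red beauty and Longshu No.7 against LK99, adjusted p alone called 5436, 7184, 8682, 7446, 7502 and 6276 genes, and the stricter threshold 953, 1496, 2021, 1320, 1894 and 1151. The construction of these thresholds gives the cause. With limma on log2(FPKM + 1), where the cause was not tested, the counts were 2044 and 2564 for the comparisons against LK99, 2514 for Red beauty against Longshu No.7, 2938 for Black kingkong against Red beauty and 2252 for Longshu No.7 against LK99. Under that setting the median log2 difference of all genes was 0.149 for Black kingkong against Red beauty and -0.135 for Red beauty against Longshu No.7.

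Listed for Black kingkong with Red beauty, with LK99 and with Longshu No.7, genes that parted the pairs numbered 777, 1219 and 325 at adjusted p alone, 76, 246 and 42 at the stricter threshold, and 179, 416 and 93 with limma. The averages called 7962, 8322 and 5192, then 996, 1513 and 619, then 1313, 1740 and 905. Without the libraries furthest from their cultivar the pairings gave 351, 781 and 191, and the pairwise counts stayed within 1.5 times. Without zinc finger proteins the regulator list had 4 tested members, 1 higher and 1 lower both for Black kingkong against Red beauty and for Longshu No.7 against LK99. Of 154 list tests, camera passed 51, 17 with an estimated correlation (34 lost), 91 with fry, which asks another question, and 45 with the block. The 17 include calls of the transport list, a single gene without a correlation to estimate. Of the 44 added, 12 passed and 4 did with an estimated correlation.

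Leaving out 1 library in turn gave 2399 to 3452 genes for Black kingkong against LK99, 3582 to 4664 for Red beauty against LK99, 4328 to 5298 for Black kingkong against Longshu No.7, 3332 to 4186 for Red beauty against Longshu No.7, 3887 to 4911 for Black kingkong against Red beauty and 3026 to 3494 for Longshu No.7 against LK99. The pairings gave 253 to 353, 606 to 750 and 111 to 181, and the averages 2803 to 3074, 3599 to 3912 and 1735 to 2125.

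Libraries of equal number share no stated batch. Of 18 pairs 1 had a correlation of deviations over 0.1 (range -0.0207 to 0.118), though 10 of 12 libraries correlated best with their own number. A small effect shared by libraries of equal number thus stays open. With the replicate block the pairwise counts were 2913, 4057, 4831, 3747, 4403 and 3232 and the pairings 301, 673 and 140, in the orders above. The flavonoid core and late anthocyanin lists then did not pass camera for Longshu No.7 against LK99 (adjusted p = 0.21 for each), nor did the flavonoid core for the average of Black kingkong and LK99 (adjusted p = 0.111). Other list calls were lost as well. Among them were the flavonoid core for Black kingkong against Longshu No.7 (camera adjusted p = 0.512) and for the average of Black kingkong and Red beauty (0.0818). B-ring hydroxylases were lost for Longshu No.7 against LK99 (camera adjusted p = 0.0519).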

Other observations

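Apart from the counts over other splits of the libraries, the tests given here were chosen only after the result was seen, as were the genes named.

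Besides photosynthesis genes, single genes of carotenoid metabolism and sugar transport were higher in Red beauty and Longshu No.7 than in Black kingkong and LK99. As lists, in the average of Black kingkong and LK99, carotenoid genes had 9 of 41 lower and 4 higher by either adjustment (camera adjusted p = 0.0313, adjusted p = 0.188 with an estimated correlation). Sucrose genes had 3 of 37 each way, or 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.226), and the median and test of that list differed in sign. No list of sugar transporters was tested. The CA1 genes, described as beta-carotene hydroxylases, enzymes that turn beta-carotene into the yellow pigment zeaxanthin, were lower in the average of Black kingkong and LK99 (92.4-fold for PGSC0003DMG400010169, edgeR adjusted p = 4.75e-05). That copy averaged 4.45 ± 2.19 CPM in Black kingkong, 348 ± 24.8 in Red beauty, 116 ± 99.1 in Longshu No.7 and 1.04 ± 0.609 in LK99 (n = 3). SWEET15 and SWEET12, sugar transporters that release sucrose from cells, had 22 ± 3.54 and 17.8 ± 4.07 CPM in Red beauty but only 2.51 ± 0.197 and 2.27 ± 0.671 in Longshu No.7. In Black kingkong they were at 0.151 ± 0.176 and 0.0976 ± 0.169 CPM, 137-fold and 185-fold lower than in Red beauty (edgeR adjusted p = 9.42e-06 and 4.35e-05), and in LK99 both were at 0. CSLG1, described as a cellulose synthase-like protein, averaged 58.3 ± 8.98 CPM in Red beauty and 128 ± 24.6 in Longshu No.7 against 0.0313 ± 0.0541 in Black kingkong and 0.107 ± 0.185 in LK99. DRM1, an auxin-repressed dormancy marker, had 30.1 ± 15.8 and 90 ± 62.9 CPM against 3.32 ± 0.415 and 6.46 ± 1.97 (average log2 fold change -3.49, edgeR adjusted p = 1.83e-05).

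Some genes outside the pigment lists were, like DFRA and AN3, high in Black kingkong and LK99 and near absent in the other cultivars. UGT75L6, described as a glucosyltransferase, averaged 44.7 ± 11.7 CPM in Black kingkong and 456 ± 222 in LK99 and was at least 16700-fold lower in Longshu No.7, where it had 0 counts, than in LK99. BEAT, described as similar to acetyl-CoA-benzylalcohol acetyltransferase, averaged 49.9 ± 14.1 and 311 ± 105 CPM, with a ratio of LK99 to Longshu No.7 of 33900 (95% interval 6090 to 1340000). CYTB5-B, a cytochrome b5, which in petunia passes electrons to the flavonoid 3',5'-hydroxylase, averaged 29.5 ± 9.29 and 157 ± 33.3 CPM and was 1370-fold lower in Longshu No.7 than in LK99 (edgeR adjusted p = 1.3e-07). WRKY44 had 0 counts in Red beauty and was at least 365-fold higher in Black kingkong (edgeR adjusted p = 2.93e-06). Another pattern was that of MLP28, described as a major latex-like protein, with 318 ± 59.5 CPM in Red beauty. It averaged 0.0841 ± 0.0924 in Black kingkong, 2.62 ± 4.54 in Longshu No.7 and 0.135 ± 0.0507 in LK99.

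Some anthocyanin pathway transcripts, those of AN3, CHS2, DFRA, RT and GSTF11, were near absent in the libraries labelled Red beauty, a cultivar named for a colour, and highest in those labelled LK99. Loss of reads from divergent alleles across the genome of Red beauty and Longshu No.7 could give such values. However, of the 9496 genes outside the pathway lists at 10 CPM or more in both other cultivars only 13 were near absent (0.137%, exact binomial 95% interval 0.0729% to 0.234%). That argues against a loss of this size across the genome, while a smaller loss was not tested. More tuber skin in both Black kingkong and LK99, by as much as these genes differed, is argued against by the periderm list. Its median log2 difference was -0.06 (interquartile range 2.01, 14 genes). Of these, 3 were higher and 1 lower, or 4 and 1 adjusted over the list alone. The mean was 0.23, and the test pointed to higher values without passing (camera adjusted p = 0.672). A smaller excess of skin was not tested. Pathway genes at 10 CPM or more in both Black kingkong and LK99 numbered 11. Their median was 5.84 with each cultivar at least at the floor. It was 10.33 for those 5 genes (10.5 at the floor), which were chosen for their near absence. The 11 genes were selected too, since the limit left out genes low in Black kingkong or LK99. Without it, medians of the lists with more than 1 gene were 0.88 (flavonoid core, 9 genes), 0.61 (B-ring, 5) and -0.26 (late, 22). More skin in LK99 alone stays open. Cutin, suberin and wax biosynthesis had 6 of 12 genes lower in Red beauty than in LK99, where 1.14 were due (hypergeometric adjusted p = 0.00483). The periderm list had 5 of 14 lower and 1 higher in Longshu No.7 against LK99, but did not pass camera (adjusted p = 0.12). An exchange of the Red beauty and LK99 labels stays open. The count of libraries that would be out of place, 6 of 6, was taken on genes chosen for this pattern and so decides nothing. A loss of reads confined to these genes and a real difference between the cultivars stay open too, and neither was tested. These cannot be told apart here because the labels state no colour and no pigment value was analysed. The library titles hold only the letters R for Red beauty and W for LK99, which the labels do not explain.

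Photosynthesis transcripts were highest in Longshu No.7, in tubers, which are not green when kept from light. Green tissue carried into single Longshu No.7 libraries is argued against, because the lowest of them (mean log2 CPM 3.82) lay 2.1 above the highest other library (1.72), with an SD within Longshu No.7 of 0.28. Green tissue carried into every Longshu No.7 library, or greening of all its tubers in light, may also give this pattern, and 3 of 3 libraries lay above every other one. It cannot be told apart from a difference between the cultivars, since no light exposure is stated for the tubers of any cultivar.

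Factors described as R2R3-MYB (MYB308), basic helix loop helix (BHLH) and WRKY44 were high with the pathway genes, which raised the hypothesis that these families are over-represented among genes higher in both Black kingkong and LK99. Of 206 tested MYB, bHLH and WRKY genes 9 were in that set (4.37%) against 392 of 22885 others (1.71%), an odds ratio of 2.62 (two-sided Fisher exact p = 0.0102). Without the genes whose values were seen before the test, 5 of 196 (2.55%) against 387 of 22878 (1.69%) remained, with an odds ratio of 1.52 (two-sided Fisher exact p = 0.393). The first test ran partly on genes that had raised the hypothesis and the second did not pass, so the hypothesis stays open. MYB113, described as MYBA1, had the opposite order, with a log2 fold change of -3.92 for Black kingkong against Red beauty (SE 0.442, edgeR adjusted p = 4.35e-05).

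The counts of called genes were set against other groupings of the same libraries. For the pairings, 1 of 100 groupings of the 12 libraries into 4 groups of 3 gave as many genes, the real one. The other groupings mix libraries of different cultivars, so low counts were due in them. The result shows only that libraries of one cultivar resemble each other more than those of other cultivars. Since the real grouping led for every pairing, this says nothing of which cultivars belong together, nor of plants if the replicates are technical. The real counts were 341 for Black kingkong with Red beauty, 730 for Black kingkong with LK99 and 156 for Black kingkong with Longshu No.7, and the highest other edgeR count was 0 for each. For the averages, again 1 of 100, the real counts of 3081, 3816 and 2015 stood against 257, 530 and 143 at most. For the pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05. On those 6 libraries alone 1 of 10, the real split, gave the highest count. It was 3075 against 1 for Black kingkong and LK99, 3802 against 1 for Red beauty and LK99, 4871 against 1 for Black kingkong and Longshu No.7, 3513 against 0 for Red beauty and Longshu No.7, 4656 against 0 for Black kingkong and Red beauty, and 2746 against 0 for Longshu No.7 and LK99.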
